A study of Homo sapiens with 8 samples.

How the data were processed

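Total RNA from 2 human neuroblastoma cell lines was enriched for messenger RNA and sequenced on a DNBseq instrument. CHLA-20 grew in IMEM with insulin, transferrin and selenium, and NGP in RPMI. Each line was treated for 6 days with DMSO or with the PRMT5 inhibitor, named JSK591 on the samples and GSK591 in the treatment description, at a dose not given as a concentration. There were 8 libraries, 2 in each of 4 groups. Whether replicates are separate cultures is not stated, so p-values of single genes measure the spread between these samples, which may be technical.

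The deposited values are raw counts per gene, 1 library per file, which the authors made with tools named as STAR and HTSeq on the GRCh38 (hg38) genome. DESeq2 is also named. Versions, the annotation and the strand setting are not given. All 58721 gene identifiers of each library, with their versions, were found in GENCODE release 29, from which symbols and coordinates were taken. Because the strand setting is unknown, counts of genes whose exons overlap another gene, and numbers of long intergenic and antisense RNAs, are less certain. Among the genes the report names, the share of exonic bases shared with another gene was highest in SRSF1 (60.7%), TEX19 (43.8%), DDIT3 (39.6%), PROKR1 (38.1%), WDR77 (36.5%), LHX4 (30.8%), ACTA2 (30.1%), UBB (28.4%), PRMT5 (27.1%) and NGFR (27.1%). A library held 33188542 to 34914902 counts assigned to genes. Reads outside genes were 5.15% to 6.86% of all counted reads, ambiguous ones 6.77% to 7.18% and reads with several alignments 19.2% to 22.0%. The 10 most abundant genes took 18.1% to 20.4% of gene counts. At this depth 3 counts, the upper limit that a count of 0 allows, correspond to at most 0.0904 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

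Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and files were prepared with Python 3.11.15 and bedtools 2.31.1. Genes were kept by filterByExpr over the 4 groups, which left 19395, and libraries were scaled by TMM. One quasi-likelihood model with the 4 groups and no block was fitted to all 8 libraries. It has 4 residual degrees of freedom and a common dispersion of 7.61e-04, a biological coefficient of variation of 2.76%. Contrasts were JSK591 against DMSO in each line, the difference of these 2 effects (NGP minus CHLA-20) and NGP DMSO against CHLA-20 DMSO. P-values were Benjamini-Hochberg adjusted over the genes tested, and 0.05 was the threshold. Log2 changes are given with their SE and CPM with the SD of 2 libraries. The SE was derived from the test's F value and is missing where a group has no counts. Pairs of replicates had a chi-square per degree of freedom of 2.16 to 3.36, treatments within a line 22.5 to 31.6 and lines 269 to 309. Replicates were not paired. Libraries with the same replicate number did not share their deviations over all genes tested (correlations -0.027 to 0.012).

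The comparisons, 26 gene lists and the rule for named genes were fixed before the data were examined. Lists were written from general knowledge of PRMT5, neuroblastoma and likely contaminating cell types: PRMT family and partners, p53 targets, S phase, mitosis, MYC targets, cytosolic ribosomal proteins, spliceosome, SR proteins and factors with detained introns, EMT and metastasis, adrenergic and mesenchymal identity, neuronal differentiation, PI3K-AKT-mTOR, FOXO targets, ATF4 and unfolded protein response, cholesterol biosynthesis, interferon-stimulated genes, homologous recombination and Fanconi, replication-dependent histones, glycolysis, respiratory chain, mitochondrially encoded genes, apoptosis, and markers of blood, epithelium, and fibroblasts and Schwann cells. Some genes are in more than 1 list. Each list with at least 5 tested members was tested by camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a contrast. Camera with the correlation estimated per list called 0, 1, 0 and 0 lists for the 4 contrasts in the order given, against 11, 6, 9 and 6 with the preset value. With the preset value camera takes genes as units, so its p-values do not measure the spread between libraries. The estimated version also uses only the 4 residual degrees of freedom, so a lost call need not come from correlated members. In CHLA-20 the mesenchymal identity had an estimated correlation of -0.018, under the preset 0.01. Its camera p still went from 1.88e-09 to 0.00231. Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, called 17, 11, 9 and 24. Setting members with 0 counts in 1 group to their floor and leaving out members at or under the floor in both groups moved the median of cholesterol genes in CHLA-20 from -0.04 to -0.01, of interferon genes in NGP from -0.26 to -0.31 and of apoptosis regulators in NGP from 0.00 to 0.04, and 9 other medians by less or not at all.

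Named genes were, per contrast, the 6 higher and 6 lower genes with the largest change among those past the threshold with an average log2 CPM of at least 1, a proper symbol and both libraries of one group above both of the other; the 2 to 4 members with the lowest p of each list described; 19 fixed genes; and the 6 higher and 6 lower genes with the largest smaller change among those called alike in both lines. That average was taken over the libraries compared, and for the difference of effects it had to be reached in each line, a reading settled after values were seen. For that contrast all JSK591 minus DMSO differences of one line had to lie beyond all those of the other. Genes with few counts in 1 line are thus not among its largest changes. Genes whose level could reveal donor sex were left out. Some genes that fit the rule are withheld and not reported here. BBC3, in the p53 paragraph, is named through the apoptosis list. For the correlation of effects the coefficient and gene set were not fixed beforehand, so 4 values are given.

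Ratios against a group with 1 to 3 counts carry a 95% exact binomial (Clopper-Pearson) interval, and a group at 0 was set to 3 counts. Alternatives tried were DESeq2 1.42.0, limma voom, RLE and total count scaling, no filter or at least 10 counts in every library, replicate number as a block (over all libraries or within lines), counts thinned to the smallest library, each line alone, leaving out each library in turn, and, for lists, fry and an estimated correlation. Removal of each library's GC trend over 20 bins of transcript GC content was added after the data were seen. The test was tried on simulated data made from these counts, with changes of known size given to well-counted genes in 1 line. Of 67 genes changed by 1.25-fold it recovered 91.0% in CHLA-20 and 88.1% in NGP, and 12 of 206 and 9 of 200 calls were false. Genes with few counts were not changed, and far fewer genes changed than were called in the real data. The rates therefore do not carry over to all genes tested. Camera called 0 of 100 random lists at p under 0.05 and detected a list shifted by 0.20. Simulated genes varied independently of each other, so this does not test whether the preset correlation is large enough for the real lists. Figures were drawn with matplotlib 3.10.9.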

Results

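Messenger RNA was counted in 2 human neuroblastoma cell lines, CHLA-20 and NGP, after 6 days with the vehicle DMSO or with a PRMT5 inhibitor. PRMT5 is the methyltransferase that places symmetric dimethyl marks on arginines of histones and splicing proteins. The sample names call the inhibitor JSK591 and the treatment description calls it GSK591. JSK591 is used here as the name on the samples, and whether both names mean one compound is not stated. There were 8 libraries in 4 groups of 2. Each library held 33188542 to 34914902 counts assigned to genes, and mitochondrially encoded genes took 19.0% to 21.4% of them. Libraries separated first by cell line, on a first principal component with 90.59% of the variance, and then by treatment, on a second with 3.49%. The 2 lines grew in different media, so a difference between lines is also a difference between media.

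In CHLA-20, the question was which genes change their level when PRMT5 is inhibited. FOS, an immediate-early transcription factor (ENSG00000170345.9, chromosome 14, 75278774 to 75282230, GRCh38), fell from 22.5 ± 0.73 to 4.45 ± 0.94 normalised counts (CPM; mean ± SD, n = 2). Its partner JUN fell by 1.09 ± 0.04 on the log2 scale (estimate ± SE), and the stress transcription factor DDIT3 fell by 1.52 ± 0.08. SLC6A2, the noradrenaline transporter (ENSG00000103546.18, chromosome 16, 55655604 to 55706192), rose from 2.43 ± 0.081 to 9.83 ± 0.35 CPM. CDKN1A, an inhibitor of cyclin-dependent kinases (ENSG00000124762.13, chromosome 6, 36676460 to 36687339), rose from 105 ± 1.6 to 167 ± 0.13 CPM.

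In this line 3285 genes were higher and 4354 lower with JSK591 out of 19395 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. Most of these changes were small, and 323 of the higher and 440 of the lower genes reached a fold of 2. The largest increases besides SLC6A2 were those of the adaptor DOK3 (log2 change 2.01 ± 0.19), the cadherin CDH6 (1.99 ± 0.14), smooth muscle actin ACTA2 (1.72 ± 0.22), the neuronal adhesion protein CNTN6 (1.71 ± 0.17) and the ETS transcription factor ETV4 (1.68 ± 0.08). The largest decreases besides FOS were those of TEX19 (-1.81 ± 0.11), MEGF6 (-1.72 ± 0.18), the fibroblast growth factor receptor FGFR4 (-1.65 ± 0.10), the receptor tyrosine kinase ERBB4 (-1.64 ± 0.18) and the glycosyltransferase MFNG (-1.58 ± 0.17). Of the 227 named genes that passed in CHLA-20, 226 had both JSK591 libraries on the same side of both DMSO libraries, and LOX did not. The rule for the largest changes required this separation, so the count is not a test of how well replicates repeat.

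Of 34 measured p53 target genes in CHLA-20, 20 rose and 4 fell (21 and 4 adjusted over the list alone). Their median log2 change was 0.34, with camera adjusted p = 4.57e-09, and adjusted p = 0.0957 with an estimated correlation. Here and below, the test with an estimated correlation also uses only 4 residual degrees of freedom, so a loss need not come from correlated members. The ubiquitin ligase MDM2 rose by 0.68 ± 0.05, the kinase PLK2 by 0.63 ± 0.05 and EDA2R, of the TNF receptor family, by 1.24 ± 0.09, while BBC3, which promotes cell death, fell by 0.80 ± 0.08. MDM4, related to MDM2, rose by 0.18 ± 0.04.

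Of 29 SR proteins and splicing factors with detained introns, which are introns kept in nuclear transcripts, 21 rose in CHLA-20 and 3 fell (21 and 4 adjusted over the list alone), with a median of 0.24. Their camera adjusted p was 2.98e-13, and adjusted p = 0.106 with an estimated correlation. HNRNPM rose by 0.96 ± 0.04, SRSF1 by 0.73 ± 0.05 and SRSF6 by 0.63 ± 0.04. Of 33 spliceosome and Sm proteins, 21 rose and 6 fell, the same counts as adjusted over the list alone (median 0.13, camera adjusted p = 0.0011, adjusted p = 0.143 with an estimated correlation). PRPF3 rose by 0.81 ± 0.05 and SNRPA fell by 0.38 ± 0.04. Of 40 DNA replication and S phase genes, 22 rose and 3 fell, unchanged when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 1.15e-06, adjusted p = 0.106 with an estimated correlation). The flap endonuclease FEN1 rose by 0.62 ± 0.04 and the licensing factor CDC6 by 0.57 ± 0.04, while CDT1 fell by 0.43 ± 0.04 (0.26 with the trend in GC content removed). Of 39 MYC and MYCN target genes, 24 rose and 7 fell, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.00158, adjusted p = 0.143 with an estimated correlation). LDHA rose by 0.41 ± 0.04, whereas CAD, the enzyme of the first steps of pyrimidine synthesis, fell by 0.72 ± 0.04, and MYC itself fell by 0.44 ± 0.03. Of 15 mitochondrially encoded genes, 8 rose and 2 fell, also when adjusted over the list alone (median 0.14, camera adjusted p = 1.31e-04, adjusted p = 0.527 with an estimated correlation).

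Of 38 mitosis genes in CHLA-20, 2 rose and 25 fell (2 and 26 adjusted over the list alone), with a median of -0.15. Their camera adjusted p was 3.15e-05, and adjusted p = 0.251 with an estimated correlation. The topoisomerase TOP2A fell by 0.54 ± 0.04 and the kinesin KIF2C by 0.38 ± 0.04. Of 33 genes of the mesenchymal neuroblastoma identity, 4 rose and 14 fell, also when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 1.63e-08, adjusted p = 0.06 with an estimated correlation). Besides FOS and JUN, the collagens COL6A1 and COL6A2 fell by 1.13 ± 0.04 and 0.74 ± 0.04. Of 32 genes of the ATF4 and unfolded protein response, 6 rose and 19 fell, also when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 8.6e-05, adjusted p = 0.251 with an estimated correlation). CEBPB fell by 1.20 ± 0.07, TRIB3 by 1.11 ± 0.06 and PCK2 by 0.84 ± 0.05, while HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.58 ± 0.04. Of 28 FOXO target genes, 4 rose and 17 fell (5 and 18 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.00247, adjusted p = 0.106 with an estimated correlation). The thioredoxin-binding protein TXNIP fell by 0.83 ± 0.04 and catalase, CAT, by 0.58 ± 0.06, while TRIB2 rose by 0.51 ± 0.04 and SESN1 by 0.65 ± 0.07. Of 26 cholesterol biosynthesis genes, 3 rose and 11 fell (4 and 11 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.039, adjusted p = 0.334 with an estimated correlation). MVD fell by 0.73 ± 0.06 and INSIG1 by 0.53 ± 0.04.

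Of the genes in the study's question, PRMT5 (ENSG00000100462.15, chromosome 14, 22920511 to 22929585) stood in CHLA-20 at 45.7 ± 0.17 CPM with DMSO and 48.2 ± 0.29 with JSK591, a log2 change of 0.08 ± 0.05 that did not pass (edgeR adjusted p = 0.233). AKT1 gave 0.00 ± 0.04 and AKT2 -0.06 ± 0.04, neither passing, while the PRMT5 partner WDR77 rose by 0.18 ± 0.07. The AKT phosphatase PHLPP1 fell by 0.88 ± 0.08. Among genes of epithelial to mesenchymal transition, SNAI1 fell by 0.70 ± 0.05, TWIST1 by 0.61 ± 0.04, SNAI2 by 0.57 ± 0.08, ZEB1 by 0.54 ± 0.04 and VIM by 0.19 ± 0.04, while CDH2 rose by 0.41 ± 0.04 and the matrix protein TNC by 1.25 ± 0.04. CDH1 gave -0.25 ± 0.31 and MYCN, at 2.34 ± 0.33 CPM with DMSO, gave 0.26 ± 0.17, neither passing, though MYCN passed at 0.62 without CHLA-20 JSK591 replicate 1.

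The other 15 lists did not pass camera in CHLA-20. Members higher and lower were 5 and 3 of 13 in the PRMT family and partners (camera adjusted p = 0.431) and 6 and 12 of 32 in the EMT and metastasis genes (0.511). They were 11 and 12 of 34 in PI3K-AKT-mTOR components (0.511) and 11 and 11 of 28 in the adrenergic neuroblastoma identity (0.624), where RET, a receptor tyrosine kinase, rose by 1.04 ± 0.04 and the transcription factor HAND2 fell by 0.55 ± 0.04. Neuronal differentiation had 12 and 13 of 36 (0.982), with the neurotrophin receptor NGFR falling by 1.33 ± 0.05. Cytosolic ribosomal proteins had 1 and 17 of 37 (0.0686), nuclear-encoded respiratory chain subunits 4 and 14 of 34 (0.0602), glycolysis 6 and 8 of 29 (0.224) and apoptosis regulators 10 and 4 of 31 (0.187). Homologous recombination and Fanconi genes had 12 and 7 of 33 (0.189), interferon-stimulated genes 3 and 5 of 26 (0.836) and replication-dependent histones 2 and 0 of 37 (0.511). Markers of other cell types had 1 and 4 of 14 for fibroblasts and Schwann cells (0.212), 0 and 1 of 8 for epithelium (0.836) and 0 and 1 of 6 for blood (0.901). Adjusted over the list alone, counts of these 15 differed for ribosomal proteins (1 and 18), adrenergic genes (12 and 11), neuronal genes (13 and 14), recombination genes (12 and 8), interferon genes (3 and 4) and histones (1 and 0). Median and mean lay below 0 and camera's direction was up for PI3K-AKT-mTOR components, and the histones' mean alone lay below 0.

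All 11 calls of lists in CHLA-20 were lost with an estimated correlation, and the cholesterol call was also lost under total count scaling (camera adjusted p = 0.0513), with the replicate number as a block (0.105), with the trend in GC content removed (0.0656) and without 6 of the 8 libraries taken singly, with the median at -0.035 to 0.018, and at -0.08 without either of the other 2. The call of WDR77 was lost without any single CHLA-20 library, with DESeq2 (adjusted p = 0.143), with no filter on low counts (0.0889) and with the replicate number as a block over all libraries (0.0501) or within each line (0.0533), and AKT1 reached 0.14 and passed with the GC trend removed. Ribosomal proteins passed with the replicate block (0.0186) and without CHLA-20 DMSO replicate 1 (0.0464) or NGP JSK591 replicate 2 (0.0186). Respiratory chain subunits passed with the block (0.042), with the GC trend removed (0.0428) and without NGP JSK591 replicate 2 (0.0377). With fry they passed too, as did EMT genes, neuronal genes, glycolysis, apoptosis regulators and fibroblast markers.

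**Figure D1:**
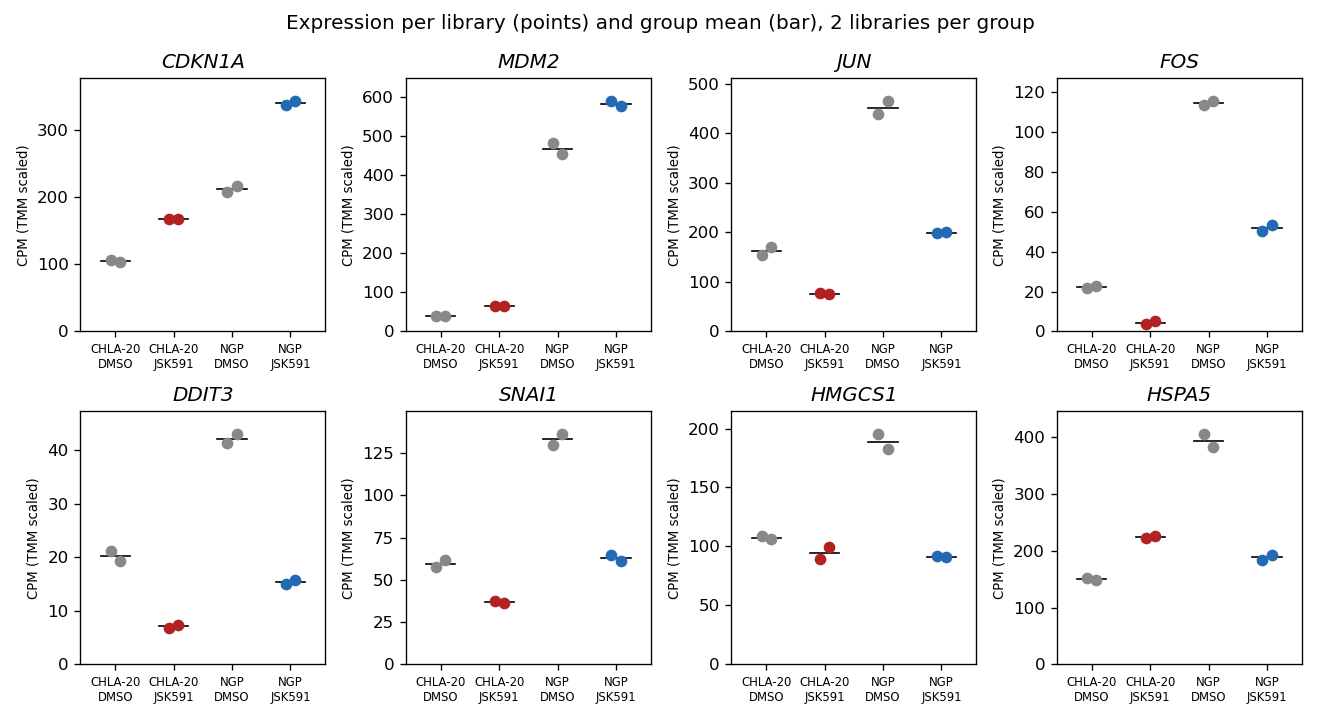
Normalised expression in CPM (y axis, starting at 0) of 8 named genes per library (points) and as the mean of each group of 2 (bars), for DMSO (grey) and JSK591 (red in CHLA-20, blue in NGP). CDKN1A and MDM2 were higher with JSK591 in both lines, JUN, FOS, DDIT3 and SNAI1 were lower in both, and HSPA5 went up in CHLA-20 (150 to 224 CPM) and down in NGP (393 to 189 CPM).

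In NGP the same question was asked of the second line. JUN (ENSG00000177606.6, chromosome 1, 58780788 to 58784327) fell from 452 ± 18 to 199 ± 1.8 CPM and FOS from 115 ± 1.1 to 51.8 ± 2.2 CPM (mean ± SD, n = 2). NPAS4, an activity-induced neuronal transcription factor (ENSG00000174576.9, chromosome 11, 66421004 to 66426707), fell from 12.5 ± 0.49 to 0.654 ± 0.22 CPM. HMGCS1, an early enzyme of cholesterol synthesis, fell by 1.05 ± 0.04 on the log2 scale, and the heat shock co-chaperone DNAJB1 fell from 263 ± 0.27 to 86.4 ± 2.4 CPM. CDKN1A rose from 211 ± 6.2 to 339 ± 3.9 CPM, and MIR34AHG, the host transcript of the microRNA miR-34a, rose by 1.58 ± 0.08.

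In NGP 3266 genes were higher and 3755 lower out of 19395 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 476 and 217 of them at a fold of at least 2. The excess of lower genes turned under total count scaling (3586 higher and 3222 lower) and with the trend in GC content removed (3948 and 3332). Long intergenic and antisense RNAs made up 485 of the higher and 99 of the lower genes, and in CHLA-20 262 and 181. These numbers are uncertain because the strand setting of the counting is not given. The other largest increases were those of INPP5D, a phosphatase of PI3K products (1.54 ± 0.13), CEP83-DT (1.51 ± 0.22), ZNF594 (1.50 ± 0.15), the prokineticin receptor PROKR1 (1.45 ± 0.22) and TMEM147-AS1 (1.41 ± 0.19). The other largest decreases were those of the transcription factors FOSB (-2.31 ± 0.14) and EGR2 (-1.52 ± 0.16), of GLIPR1 (-1.60 ± 0.15) and of the matrix protein CYR61, also named CCN1 (-1.47 ± 0.10). Of the 221 named genes that passed in NGP, 220 had both JSK591 libraries on the same side of both DMSO libraries, and MT-ND6 did not. This count too follows in part from the rule for named genes.

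Of 26 cholesterol biosynthesis genes in NGP, 22 fell and 2 rose, also when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 2.62e-26). This was the one call of the 26 fixed lists that held with an estimated correlation (adjusted p = 0.0279 with an estimated correlation). MSMO1 fell by 1.14 ± 0.05, FDFT1 by 0.87 ± 0.04 and IDI1 by 0.86 ± 0.05, all enzymes of the pathway. Of 32 genes of the ATF4 and unfolded protein response, 24 fell and 1 rose, also when adjusted over the list alone (median -0.33, camera adjusted p = 1.02e-20, adjusted p = 0.0508 with an estimated correlation). DDIT3 fell by 1.45 ± 0.07, HSPA5 by 1.06 ± 0.04, the amino acid transporter subunit SLC3A2 by 0.76 ± 0.04 and HERPUD1 by 0.67 ± 0.04.

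Of 33 mesenchymal identity genes in NGP, 11 fell and 5 rose (12 and 5 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 8.21e-06, adjusted p = 0.0508 with an estimated correlation). ID1, an inhibitor of helix-loop-helix transcription factors, fell by 1.05 ± 0.04. Of 38 mitosis genes, 22 fell and 4 rose (24 and 4 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 1.42e-05, adjusted p = 0.338 with an estimated correlation). Cyclin A2, CCNA2, fell by 0.42 ± 0.04 and TOP2A by 0.35 ± 0.04. Of 34 p53 target genes, 15 rose and 6 fell (17 and 6 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00238, adjusted p = 0.327 with an estimated correlation). SESN1 rose by 0.64 ± 0.07, the death receptor TNFRSF10B by 0.50 ± 0.04 and MDM2 by 0.32 ± 0.04, while MDM4 gave 0.04 ± 0.04 without passing. Of 15 mitochondrially encoded genes, 11 rose and 1 fell, also when adjusted over the list alone (median 0.14, camera adjusted p = 5.84e-05, adjusted p = 0.575 with an estimated correlation). MT-ND2 rose by 0.52 ± 0.04 and MT-ND1 by 0.48 ± 0.04, while the ribosomal RNA MT-RNR1 fell by 0.34 ± 0.04.

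Of the genes in the study's question, AKT1 (ENSG00000142208.16, chromosome 14, 104769349 to 104795751) rose in NGP from 72.0 ± 0.42 to 92.8 ± 1.8 CPM (log2 change 0.37 ± 0.04, edgeR adjusted p = 4.58e-10). PRMT5 gave -0.06 ± 0.05, WDR77 0.16 ± 0.08 and AKT2 -0.05 ± 0.04, none passing, though AKT2 passed at -0.14 without NGP DMSO replicate 1. SNAI1 fell by 1.08 ± 0.05, VIM by 0.51 ± 0.04, ZEB1 by 0.35 ± 0.04 and CDH2 by 0.13 ± 0.04 (0.08 with the GC trend removed), while SNAI2 gave 0.19 ± 0.09 and TWIST1 -0.05 ± 0.04 without passing. SNAI2 passed under total count scaling (0.21), with at least 10 counts in every library (0.20) and with the GC trend removed (0.24), and with the last WDR77 (0.20) and MDM4 (0.09) passed as well. CDH1 had 13 counts with DMSO and 0 with JSK591, 4.45-fold lower with the 0 set to a floor of 3 counts over the group. The counting error of the 13 is not in this value, so it is not a lower bound. MYCN fell by 0.21 ± 0.04 from 2320 ± 94 CPM, and MYC, at 0.972 ± 0.19 CPM with DMSO, fell by 0.88 ± 0.28.

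The other 20 lists did not pass camera in NGP. Members higher and lower were 4 and 4 of 13 in the PRMT family and partners (camera adjusted p = 0.91), where RIOK1 fell by 0.38 ± 0.05 and PRMT6 rose by 0.43 ± 0.06. They were 11 and 14 of 40 in S phase genes (0.873), 8 and 9 of 39 in MYC and MYCN targets (0.941), 2 and 11 of 33 in spliceosome and Sm proteins (0.169) and 9 and 11 of 29 in SR proteins and splicing factors (0.91). In the last, the kinases CLK1 and CLK4 fell by 0.71 ± 0.05 and 0.61 ± 0.06, and SRSF5 rose by 0.58 ± 0.04. EMT and metastasis genes had 6 and 11 of 32 (0.245), PI3K-AKT-mTOR components 9 and 6 of 34 (0.824), FOXO targets 7 and 9 of 28 (0.0965) and adrenergic genes 8 and 9 of 28 (0.245). Among them ALK of the adrenergic list rose by 0.62 ± 0.05, and KLF6 of the FOXO list fell by 1.18 ± 0.05. Neuronal differentiation had 9 and 13 of 36 (0.225), glycolysis 6 and 12 of 29 (0.143), respiratory chain subunits 0 and 10 of 34 (0.165), ribosomal proteins 4 and 3 of 37 (0.873) and apoptosis regulators 9 and 5 of 31 (0.824). Recombination and Fanconi genes had 8 and 12 of 33 (0.396), histones 5 and 9 of 37 (0.91) and interferon-stimulated genes 3 and 3 of 26 (0.824). Marker lists had 2 and 5 of 14 for fibroblasts and Schwann cells (0.597), 0 and 1 of 8 for epithelium (0.824) and 0 and 1 of 6 for blood (0.824). Adjusted over the list alone, counts of these 20 differed for spliceosome proteins (2 and 12), adrenergic genes (9 and 9), neuronal genes (9 and 15), glycolysis (6 and 14), respiratory chain subunits (0 and 7), ribosomal proteins (4 and 2), apoptosis regulators (9 and 7) and recombination genes (8 and 13). Median, mean and camera's direction did not share a sign for PRMT partners, S phase genes, MYC targets, ribosomal proteins, SR proteins, PI3K-AKT-mTOR components, histones and apoptosis regulators.

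The mitochondrial call was also lost with fry (adjusted p = 0.0526), and its median fell to 0.09 without NGP DMSO replicate 2 or NGP JSK591 replicate 2. MYCN's call was lost with DESeq2 (adjusted p = 0.564), and MYC's was lost without NGP DMSO replicate 2 (log2 change -0.68) or without NGP JSK591 replicate 1 (-0.82). DESeq2 gave 2083 higher genes in NGP, under 3266 by more than 1.5 times. Spliceosome proteins (camera adjusted p = 0.0205) and glycolysis (0.0305) passed without NGP DMSO replicate 1, and respiratory chain subunits without that library (0.0305), CHLA-20 DMSO replicate 2 (0.0338) or NGP JSK591 replicate 2 (0.0267). These 3 lists, EMT genes, neuronal genes and FOXO targets passed with fry.

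**Figure D2:**
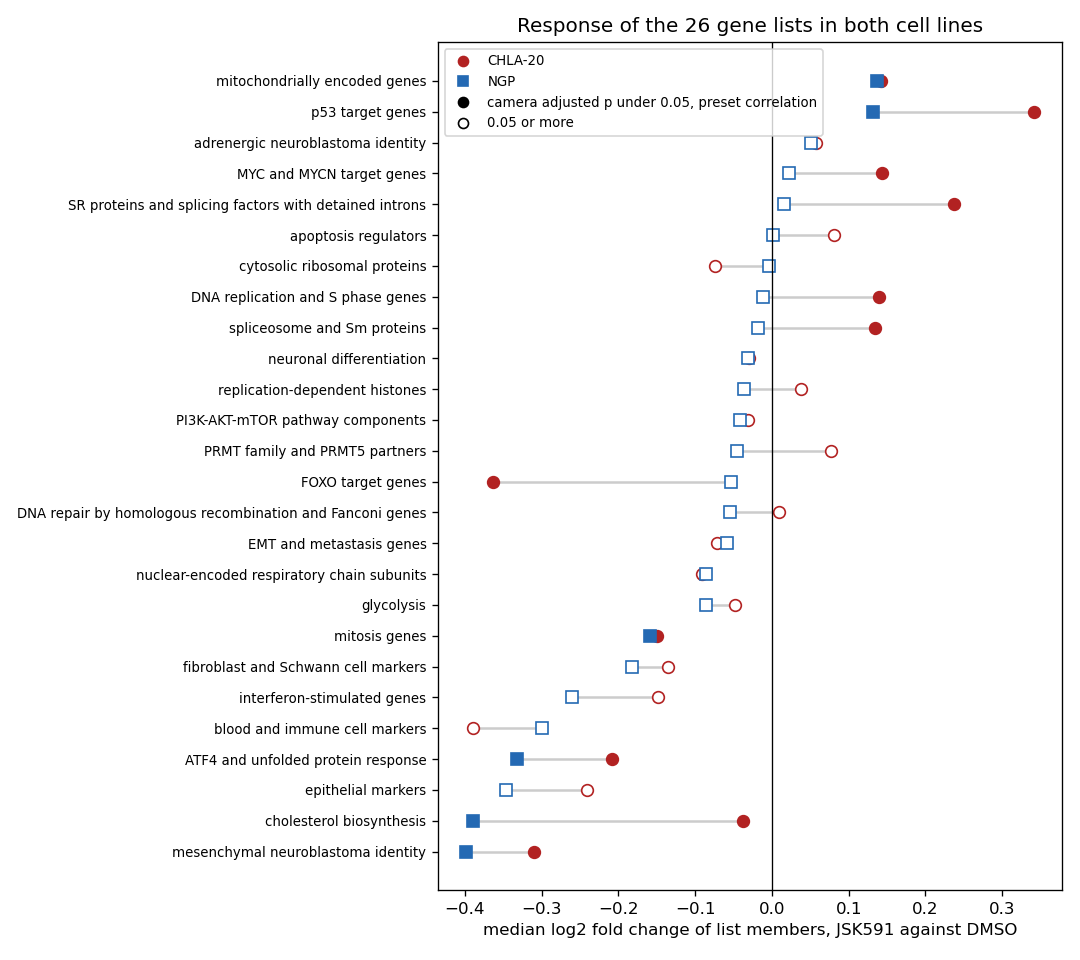
Median log2 fold change of the members of 26 gene lists (x axis) in CHLA-20 (red circles) and NGP (blue squares), filled where camera with a preset correlation gave an adjusted p under 0.05. Mitosis, mesenchymal identity and ATF4 lists lay below 0 in both lines, p53 targets above 0 in both, and cholesterol biosynthesis lay at -0.39 in NGP and -0.04 in CHLA-20.

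Both lines were then set side by side, and the difference of their responses was tested directly. Genes higher in both numbered 1109, against 553 for independent lists (odds ratio 3.30, two-sided Fisher's exact test p = 8.04e-154), and genes lower in both 1741, against 843 (odds ratio 4.31, p = 4.45e-297). These tests treat genes as independent units, which they are not, so the p-values do not measure the spread between libraries. Opposite calls numbered 373 and 461, against 636 and 733 for independent lists. TOMM5, of the mitochondrial import machinery, rose by 1.46 ± 0.16 in CHLA-20 and 1.07 ± 0.14 in NGP, the cytokine LIF by 0.97 ± 0.18 and 1.18 ± 0.17, and TNC by 1.25 ± 0.04 and 1.03 ± 0.13. Also higher in both with the largest smaller change were ZNF587B, the leukotriene receptor LTB4R and the homeobox gene LHX4. Besides FOS, JUN and DDIT3, the genes lower in both with the largest smaller change were the receptor FGFR4 (-1.65 ± 0.10 and -0.94 ± 0.09), CLYBL (-1.35 ± 0.13 and -0.99 ± 0.16) and the long RNA OLMALINC (-1.52 ± 0.05 and -0.92 ± 0.06). Across all 19395 genes, which are not independent replicates, Pearson's r of the 2 effects was 0.126 and Spearman's rho 0.235. Across 11595 genes with a log2 CPM of at least 1 in each line, both were 0.361.

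By the interaction, 2950 genes had a higher and 2418 a lower effect in NGP than in CHLA-20 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Lower ones were in excess instead under RLE scaling (2670 higher and 2773 lower), with DESeq2 (1850 and 2022) and without CHLA-20 DMSO replicate 2 (2066 and 2638), NGP DMSO replicate 1 (1989 and 2698), NGP DMSO replicate 2 (2174 and 2708) or NGP JSK591 replicate 1 (1999 and 2604), so which side is larger depends on the processing. HSPA5 (ENSG00000044574.7, chromosome 9, 125234853 to 125241330) rose in CHLA-20 and fell in NGP, with a difference of -1.64 ± 0.05, and DNAJB1 rose by 0.39 ± 0.04 in CHLA-20 and fell by 1.60 ± 0.04 in NGP. SLC6A2 differed by -2.28 ± 0.13, CNTN6 by -2.39 ± 0.24, CDH6 by -1.80 ± 0.19 and the RAS-like protein RERG by -1.73 ± 0.17. In the other direction MFNG differed by 2.01 ± 0.20, MEGF6 by 1.95 ± 0.22, ERBB4 by 1.89 ± 0.20, LINC00599 by 1.74 ± 0.10, OSGIN1 by 1.72 ± 0.26 and MAN1C1 by 1.70 ± 0.27. AKT1 differed by 0.36 ± 0.06 (0.21 with the trend in GC content removed), TWIST1 by 0.56 ± 0.05 and CDH2 by -0.55 ± 0.05. CDKN1A differed by 0.01 ± 0.05 and PRMT5 by -0.13 ± 0.07, neither passing.

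Among lists, cholesterol biosynthesis had a lower effect in NGP for 17 of 26 members and a higher one for 1, also when adjusted over the list alone (median difference -0.34, camera adjusted p = 2.09e-13, adjusted p = 0.1 with an estimated correlation). HMGCS1 differed by -0.86 ± 0.06 and IDI1 by -0.89 ± 0.07. SR proteins and splicing factors were lower for 20 of 29 and higher for 2 (21 and 2 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 1.16e-12, adjusted p = 0.146 with an estimated correlation). SRSF3 differed by -0.70 ± 0.05. Spliceosome proteins were lower for 16 of 33 and higher for 3 (17 and 3 adjusted over the list alone), with camera adjusted p = 3.39e-06 and adjusted p = 0.146 with an estimated correlation. S phase genes were lower for 20 of 40 and higher for 4 (21 and 4 adjusted over the list alone), with camera adjusted p = 1.34e-05 and adjusted p = 0.146 with an estimated correlation; MCM10 differed by -0.59 ± 0.06. MYC targets were lower for 12 of 39 and higher for 4 (14 and 5 adjusted over the list alone), with camera adjusted p = 0.00508 and adjusted p = 0.201 with an estimated correlation. For p53 targets 10 of 34 were lower and 3 higher, also when adjusted over the list alone, with camera adjusted p = 0.00508 and adjusted p = 0.232 with an estimated correlation. The ATF4 and unfolded protein response had 12 of 32 lower and 5 higher (12 and 6 adjusted over the list alone), with camera adjusted p = 0.00152 and adjusted p = 0.382 with an estimated correlation. Recombination and Fanconi genes had 10 of 33 lower and 4 higher (11 and 4 adjusted over the list alone), with camera adjusted p = 0.0414 and adjusted p = 0.758 with an estimated correlation. The JSK591 effect followed transcript GC content with a slope of -0.08 in CHLA-20 and 0.04 in NGP (log2 per 10 points of GC), and with that trend removed the medians were -0.37 for cholesterol, -0.12 for SR protein, -0.13 for S phase and -0.07 for ATF4 genes. Mesenchymal identity genes had 11 of 33 higher and 5 lower, also when adjusted over the list alone, with camera adjusted p = 0.0414 and adjusted p = 0.201 with an estimated correlation.

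The remaining 17 lists had camera adjusted p of 0.054 (ribosomal proteins) to 0.871 for the interaction. Ribosomal proteins passed, with a higher effect in NGP, under total count scaling (0.0335), with the replicate block (0.0243), with the GC trend removed (0.0226) and without CHLA-20 DMSO replicate 1 (0.0491) or NGP JSK591 replicate 1 (0.00375), and FOXO targets passed with fry (0.0394). Signs of median, mean and camera's direction differed for EMT genes, the mesenchymal identity (median 0.04, mean -0.13, direction up), neuronal genes, PI3K-AKT-mTOR components, histones, glycolysis, respiratory chain subunits and fibroblast markers. The mesenchymal call was lost with the replicate block, with the GC trend removed and without each of the 8 libraries (adjusted p = 0.0633 to 0.133), and the recombination call with fry (0.114), with the GC trend removed (0.261) and without CHLA-20 JSK591 replicate 2 (0.0737), NGP DMSO replicate 1 (0.0572) or NGP JSK591 replicate 2 (0.0564). Without 1 library the median differences ranged from -0.17 to 0.05 for the mesenchymal identity, from -0.168 to -0.076 for recombination genes, from -0.124 to -0.053 for ATF4 genes and from -0.20 to -0.13 for p53 targets. MYCN's difference of -0.47 ± 0.18 was lost with DESeq2, limma voom, total count scaling, no filter on low counts and at least 10 counts in every library, as well as without CHLA-20 DMSO replicate 2 (-0.37) or NGP DMSO replicate 2 (-0.47), and was 0 without CHLA-20 JSK591 replicate 2 and -0.83 without CHLA-20 JSK591 replicate 1. ZEB1's of 0.19 ± 0.06 was lost without CHLA-20 DMSO replicate 2 (0.16), CHLA-20 JSK591 replicate 1 (0.17), NGP DMSO replicate 2 (0.11) or NGP JSK591 replicate 1 (0.16) and reached 0.30 with the GC trend removed, and DESeq2 gave 1850 genes with a higher effect in NGP, 735 higher in both and 502 called in opposite directions.

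With DMSO, the lines differed far more than treatment moved either. MYCN (ENSG00000134323.11, chromosome 2, 15940564 to 15947007) stood at 2320 ± 94 CPM in NGP and 2.34 ± 0.33 in CHLA-20, and MYC (ENSG00000136997.17, chromosome 8, 127735434 to 127741434) at 0.972 ± 0.19 and 1400 ± 7.3 CPM (mean ± SD, n = 2). TH, the first enzyme of catecholamine synthesis, stood at 0.762 ± 0.11 CPM in NGP and 1380 ± 40 in CHLA-20. UBB, a ubiquitin gene, had 2 counts in NGP and 20945 in CHLA-20, a ratio of 1.04e+04 (95% counting interval 2870 to 85700). SEPT14, a septin, had 8187 counts in NGP and 0 in CHLA-20, at least 2750-fold higher against the floor of 3 counts over the group.

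In NGP 7089 genes were higher and 7548 lower than in CHLA-20, with 3055 and 3783 at a fold of at least 2 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The excess of lower genes turned under total count scaling (7357 higher and 7255 lower) and without NGP DMSO replicate 1 (7103 and 6876), NGP DMSO replicate 2 (7067 and 6994) or NGP JSK591 replicate 1 (7552 and 7395). The other largest increases in NGP were ARHGAP36 (log2 difference 11.56 ± 0.09), PRRX1, a transcription factor of the mesenchymal identity (10.49 ± 0.15), and NRN1, SYT6 and MAGEC2, which had 1, 2 and 3 counts in CHLA-20. Their ratios were 4720 (846 to 1.86e+05), 1960 (541 to 1.62e+04) and 1860 (638 to 9040). Among genes that met the limits of the rule for named genes, the other largest decreases were CYGB, CCDC144NL-AS1, CYYR1 and LINC02381, each with 2 counts in NGP and 3372 to 14234 in CHLA-20. Their ratios were 7050 (1950 to 5.82e+04), 2560 (710 to 2.12e+04), 2090 (579 to 1.73e+04) and 1670 (462 to 1.38e+04). All 277 named genes that passed here had both libraries of one line above both of the other, which again follows in part from the rule for named genes.

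Of 28 adrenergic identity genes, 20 were lower and 8 higher in NGP, also when adjusted over the list alone, with a median of -0.95 (camera adjusted p = 0.00311, adjusted p = 0.425 with an estimated correlation). RET was lower by a log2 difference of -4.48 ± 0.06. Of 36 neuronal differentiation genes, 27 were lower and 8 higher, also when adjusted over the list alone (median -0.83, camera adjusted p = 1.39e-05, adjusted p = 0.236 with an estimated correlation), with the neurofilament NEFL at -5.64 ± 0.06. Glycolysis had 21 of 29 lower and 3 higher, also when adjusted over the list alone (median -0.51, camera adjusted p = 0.00899, adjusted p = 0.425 with an estimated correlation). Mitosis genes had 25 of 38 lower and 6 higher, also when adjusted over the list alone (median -0.32, camera adjusted p = 0.0164, adjusted p = 0.691 with an estimated correlation). Of 37 replication-dependent histones, 33 were higher in NGP and 0 lower, also when adjusted over the list alone (median 2.18, camera adjusted p = 1.20e-05, adjusted p = 0.248 with an estimated correlation). How much histone RNA the enrichment for messenger RNA kept in each line was not measured, so this difference may not be one of expression. Spliceosome proteins had 20 of 33 higher and 9 lower, also when adjusted over the list alone (median 0.20, camera adjusted p = 0.0195, adjusted p = 0.425 with an estimated correlation). AKT1 was lower in NGP by a log2 difference of -0.67 ± 0.04 (-0.38 with the GC trend removed), TWIST1 by -2.53 ± 0.04 and VIM by -1.30 ± 0.04, while MDM2 was higher by 3.53 ± 0.04, SNAI1 by 1.16 ± 0.05 and PRMT5 by 0.44 ± 0.05.

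The remaining 20 lists had camera adjusted p of 0.0761 (cholesterol biosynthesis) to 0.901 (blood markers) between the lines. Median, mean and camera's direction did not share a sign for p53 targets, MYC targets and FOXO targets. No call of a list between the lines held with an estimated correlation, and that of AKT2 (0.12 ± 0.04) was lost without CHLA-20 DMSO replicate 1 (0.09) or NGP DMSO replicate 2 (0.09), while it reached 0.23 without NGP DMSO replicate 1 and 0.30 with the GC trend removed. Cholesterol genes passed with the GC trend removed (camera adjusted p = 0.0234) and without NGP DMSO replicate 1 (0.048).

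**Figure D3:**
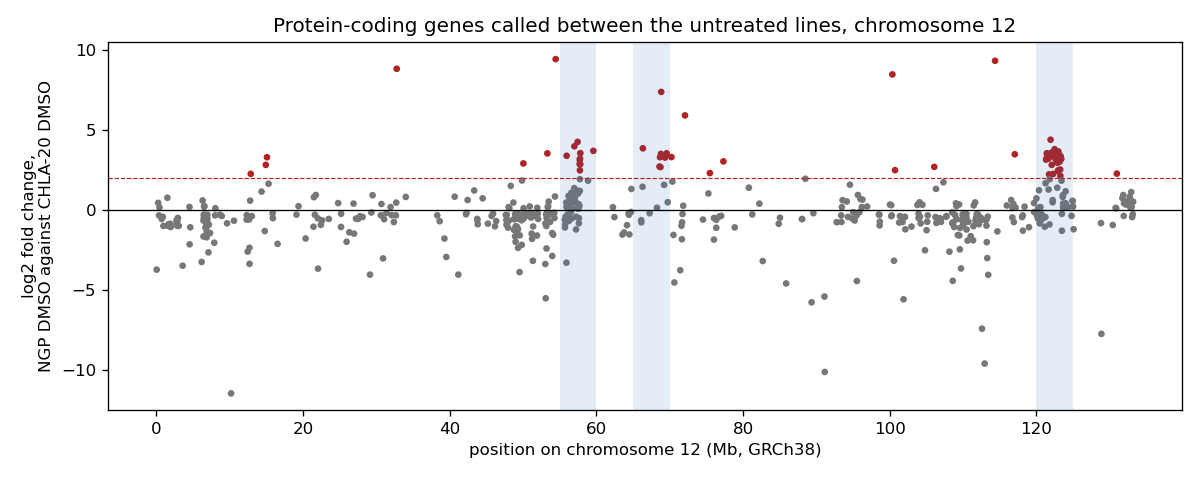
Log2 difference between NGP and CHLA-20, both with DMSO (y axis), against position on chromosome 12 in Mb (x axis) for 562 protein-coding genes that passed the test and had an average log2 CPM above 1, with genes at least 4-fold higher in NGP in red above the dashed line. Shaded stretches of 5 Mb held 25, 19 and 51 tested genes of any type at least 4-fold higher in NGP, with CDK4 in the first and MDM2 in the second.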

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

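The test of where the most strongly shifted genes lie on chromosome 12, and removal of the GC trend as a setting, were chosen only after results were seen. Slopes over GC content were not among the items fixed before the data were examined, and the other tests named here were planned. By the interaction in edgeR's quasi-likelihood test, 2950 genes had a higher and 2418 a lower response to JSK591 in NGP than in CHLA-20, an excess that turned under RLE scaling (2670 and 2773). Higher in NGP were the responses of MFNG (2.01), MEGF6 (1.95), ERBB4 (1.89), LINC00599 (1.74), OSGIN1 (1.72) and MAN1C1 (1.70), as log2 differences. Lower in NGP were those of CNTN6 (-2.39), SLC6A2 (-2.28), DNAJB1 (-1.99), CDH6 (-1.80), RERG (-1.73) and HSPA5 (-1.64). Lists differed with a median of -0.129 for p53 targets, -0.169 for S phase genes, -0.110 for MYC targets, -0.165 for spliceosome proteins, -0.194 for SR proteins, -0.343 for cholesterol biosynthesis, -0.069 for the ATF4 and unfolded protein response, -0.071 for recombination and Fanconi genes and 0.041 for the mesenchymal identity, all by camera with a preset correlation. None of these 9 differences of lists passed with an estimated correlation. The last also missed the threshold without each of the 8 libraries, where its median ranged from -0.173 to 0.053, and that of recombination genes missed it with the GC trend removed and ranged from -0.168 to -0.076 without 1 library. For p53 targets that range was -0.204 to -0.129.

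The first pattern is that 4 of these lists responded differently in the lines. Removing each library's GC trend left median differences of -0.371 for cholesterol genes, -0.120 for SR proteins and -0.134 for S phase genes, with camera adjusted p of 2.03e-17, 2.25e-08 and 1.75e-07, and the smaller of the medians under RLE and total count scaling was -0.332, -0.182 and -0.158. This argues against GC content as the whole source of these 3. The p-values used the preset correlation, and an estimated one was not tried with the trend removed. A change of scaling moves all genes nearly alike: the median difference over all genes was 0.028, with 0.003 under RLE and 0.039 under total counts. The scaling test therefore shows only that the choice among these scalings is too small to make these 3 medians. For the ATF4 and unfolded protein response the camera adjusted p with the GC trend removed was 5.5e-06 against 0.00152 before, which argues against GC content as the whole source of that call as well. Its medians were -0.069 before, -0.065 with the trend removed, -0.058 under total count scaling and -0.093 under RLE, with -0.124 to -0.053 without 1 library, and quartiles of -0.323 and 0.152 before and of -0.331 and 0.112 with the trend removed lie on both sides of 0, so for its median scaling cannot be told apart from a response of the cells. A difference between the cell lines is a candidate explanation and stays open beside the media, which differ in the same way.

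The second pattern is that the JSK591 effect followed transcript GC content, with a slope of -0.081 ± 0.004 (log2 per 10 points of GC, ± SE) in CHLA-20 and 0.038 ± 0.003 in NGP over 9684 protein-coding genes. A GC bias of single libraries could contribute, since the 2 DMSO replicates of NGP differed by a slope of 0.045, more than treatment in that line. Other replicate pairs had 0.025, -0.036 and -0.002, all smaller in size than the CHLA-20 slope. A bias shared by the libraries of a group could contribute too. The 872 lincRNA and antisense genes, taken at a log2 CPM above 0, had slopes of 0.042 ± 0.024 in NGP and -0.083 ± 0.026 in CHLA-20. These were close to those of coding genes, taken above 3. A response of the cells could give equal slopes as well. With the strand setting unknown, antisense counts may also hold reads of coding genes, so this comparison cannot separate the explanations. With the trend removed, the interaction had 5265 calls, 4357 of them shared in sign with the 5368 before, and a response of GC-rich genes in the cells stays open as well.

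The third pattern is that genes far higher in NGP than in CHLA-20, both with DMSO, lay close together on chromosome 12. Between 120000001 and 125000000, 51 of 119 tested genes were at least 4-fold higher, whereas in 10000 random placements the largest count of any window of 5 Mb on this chromosome was 22 and on any chromosome 31. The windows from 55000001 and 65000001, with CDK4 and MDM2, held 25 of 113 and 19 of 35. The count of 25 was above 22 but under 31. That of 19 was under both, though above 16, the 95th percentile of the placements on this chromosome. These counts do not allow for how many genes a window holds. The window from 25000001 on chromosome 6 held 28 of 96, mostly histone genes, so related genes that lie together can give such a count too. A shared regional cause such as DNA copy number is a candidate explanation, but copy number was not measured here. The window from 15000001 on chromosome 2, with MYCN, held 16 of 28.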

How the results depend on the processing

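Removal of the GC trend was chosen only after results were seen; all other alternatives here were planned. Of 231 results of the named genes reported that passed, compared with 4210 alternative values, 4185 kept direction and threshold, 24 missed the threshold and 1 turned to 0. Of 32 calls of lists, 392 of 448 alternatives kept the call, 56 missed the threshold and none turned. No result that had not passed did so in the opposite direction, except PI3K-AKT-mTOR components between the lines under fry (median 0.011). In the same direction, lists that had not passed did so in 48 of 1008 alternatives, 30 of them with fry, and genes in 15 of 316, among them MDM4 for the interaction (DESeq2, RLE and 5 of the fits without 1 library). Counts of genes stayed within 1.5 times under every alternative except DESeq2, which gave 2083 higher genes in NGP, 1850 with a higher effect in NGP, 735 higher in both lines and 502 called in opposite directions. Over the fits without 1 library, where the lone sample of its group is assumed to vary like the other groups, higher genes ranged from 2484 to 3804 in CHLA-20 and from 2220 to 3285 in NGP. Depth differed little between libraries, so thinning to the smallest moved calls little (3287 higher and 4296 lower in CHLA-20). Replicate blocks gave 3275 higher and 4369 lower genes in CHLA-20 and 3256 and 3757 in NGP. With the GC trend removed, results that still passed changed by more than 1.5 times for AKT1 (0.208 for the interaction, -0.375 between lines), AKT2 (0.305 between lines), CDH2 in NGP (-0.082), ZEB1 for the interaction (0.297), CDT1 in CHLA-20 (-0.256), LSM7 of the spliceosome list in CHLA-20 (-0.201, against -0.332 before) and SR proteins for the interaction (-0.120). Causes of the changes below were not tested, apart from settings that test fewer genes or use fewer libraries.

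Spearman's rho between the effects was 0.320 with at least 10 counts in every library and 0.260 with the GC trend removed, and 0.197 to 0.229 without 1 library. Pearson's r was 0.314 with at least 10 counts, 0.142 with DESeq2 and 0.0975 to 0.130 without 1 library. Both rose where genes with few counts were left out. Lists called numbered 0 in CHLA-20, 1 in NGP, 0 for the interaction and 0 between lines with an estimated correlation, and 17 in CHLA-20, 11 in NGP and 24 between lines with fry.

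Lists that had not passed turned camera's or fry's direction, at the medians given, which for some kept their sign. For neuronal differentiation in CHLA-20 these were -0.022 (RLE), -0.016 (total counts), -0.030 (replicate block) and -0.007 (GC trend removed). In NGP they were -0.021 (total counts) and -0.036 (GC) for PRMT partners, 0.047 (total counts), 0.022 (block) and 0.051 (GC) for MYC targets, -0.021 (RLE) for ribosomal proteins, 0 (RLE) for SR proteins and -0.003 (GC) for histones. For the interaction they were -0.004 (RLE) for mitosis, 0.072 (fry) and 0.118 (GC) for EMT genes, 0.008 (fry) for PI3K-AKT-mTOR, -0.010 (fry) and -0.034 (RLE) for interferon genes, and -0.007 (fry), -0.007 (block) and 0.057 (GC) for mitochondrially encoded genes. Between lines FOXO targets stood at 0.128 (fry) and 0.114 (GC).

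Without 1 library, medians of lists that turned ranged in CHLA-20 from -0.038 to -0.001 for neuronal genes, -0.300 to -0.015 for interferon genes and -0.791 to 0.000 for blood markers. In NGP they ranged from -0.091 to -0.038 for PRMT partners, -0.041 to -0.006 for S phase, -0.062 to 0.028 for ribosomal proteins, -0.016 to 0.015 for SR proteins, -0.062 to -0.019 for PI3K-AKT-mTOR and -0.122 to 0.077 for histones. For the interaction they ranged from -0.041 to 0.025 for mitosis, -0.073 to 0.014 for PI3K-AKT-mTOR, -0.144 to 0.106 for interferon genes, -0.045 to 0.022 for respiratory chain subunits, -0.045 to 0.005 for mitochondrially encoded genes, -0.533 to 0.734 for epithelial markers and -0.174 to 0.029 for fibroblast markers. Between lines blood markers ranged from -0.996 to -0.428.

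Genes that turned without passing were WDR77 for the interaction (0.003 with the GC trend removed), AKT2 in CHLA-20 (0.024, GC) and for the interaction (-0.015 with DESeq2 and with RLE, -0.075 with GC) and CDKN1A for the interaction (-0.011 with DESeq2 and with RLE, -0.069 with GC). Without 1 library the ranges were -0.124 to 0.006 for WDR77, -0.108 to 0.036 for AKT2 and -0.071 to 0.013 for CDKN1A in the interaction, -0.031 to 0.066 for AKT1 in CHLA-20, and -0.008 to 0.070 for MDM4 in NGP. MYCN ranged from -0.209 to 0.621 in CHLA-20, where it has few counts, passing without CHLA-20 JSK591 replicate 1, and from -0.830 to 0 for the interaction, at 0 without CHLA-20 JSK591 replicate 2.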

Other observations

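Tests of the 3 lists in this part were chosen only after results were seen. Lists of immediate-early, heat shock and ERK output genes were written after single genes had drawn attention (FOS, JUN, EGR1, ARC, NPAS4, KLF6, DNAJB1, HSPH1, ETV4, DUSP6 and CCND1), and members already seen or in a fixed list were left out of the test. Of 12 remaining immediate-early genes, 9 fell and 1 rose with JSK591 in NGP (median -0.46, camera adjusted p = 1.46e-05 over 6 tests, adjusted p = 0.105 with an estimated correlation). In CHLA-20, 5 fell and 1 rose (median -0.29, camera adjusted p = 0.244). Of 14 heat shock genes, 8 rose and 5 fell in CHLA-20 (median 0.18, adjusted p = 0.0162), and 3 rose and 7 fell in NGP (median -0.14, adjusted p = 0.0162), with adjusted p = 0.28 with an estimated correlation in each line. Of 12 genes that ERK signalling induces, such as SPRY2, DUSP4 and ETV5, 7 rose and 0 fell in CHLA-20 (median 0.21, camera adjusted p = 4.33e-06, adjusted p = 0.0385 with an estimated correlation). In NGP, 4 rose and 1 fell (median 0.03, camera adjusted p = 0.22), and the difference between lines was not tested for these lists.

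One hypothesis is that ERK output may rise with JSK591 in CHLA-20 (4.33e-06, and 0.0385 with an estimated correlation) while immediate-early transcription may fall in NGP (1.46e-05, but not past the threshold at 0.105 with an estimated correlation). The second part does not place that fall in NGP alone, since the same 12 genes had a median of -0.29 in CHLA-20. FOS and JUN, which fell in both lines, are themselves induced through ERK, so the first part is not a statement about the pathway as a whole. Protein phosphorylation was not measured here, and the level of phosphorylated ERK in both lines with and without JSK591 would test the first part.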
